A study of Mus musculus with 2 samples.

How the data were processed

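Single cells from the lungs of 3-month-old and 18-month-old mice treated with saline or LPS (2.5 mg/kg) for 24 h were sorted for EpCAM, with dead cells excluded by DAPI. Per the labels, each group carried its own hashtag antibody, the 4 groups were pooled in equal cell number on 1 lane, and the experiment was performed on 2 lanes. The deposited tables hold raw UMI counts per gene and barcode, with no normalization, in 1 table per group and lane. The tables hold 31053 genes (30934 with a symbol in GENCODE M21, build GRCm38, and 119 without) and 4 hashtag rows, which were kept apart from the genes. The labels list Cell Ranger 3.1.0, STAR, bcl2fastq, Seurat 3.1 and 3.1.5, R 3.6.3 and genome build mm10; the role and order of these tools, and how barcodes were assigned to hashtags, are not given in the sources used here. Each deposited barcode had at least 500 UMIs, and the dominant hashtag held a median of 98.7% to 99.5% of the hashtag counts per library. A deposited list of barcodes was not used here.

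The total depth was 85889264 UMIs over 14048 barcodes, with 6228266 to 15435789 per library. Barcodes with under 500 detected genes or over 20% mitochondrial UMIs were removed (2803 of 14048; 12.1% to 34.7% per library), which left 11245. Doublets were called per lane with scrublet in scanpy 1.11.5 (expected share 2%), which marked 13 cells (7 of 5433 and 6 of 5812); this is few for pooled lanes, and leaving out the 3% of cells with the highest scores was therefore added as an alternative after the data were seen. The remaining 11232 cells were clustered with 2000 variable genes, 30 principal components, 20 nearest neighbours and leidenalg 0.10.2 at resolution 1, which gave 22 clusters. A cluster was named by marker lists of 21 classes: its name is the class with the highest mean log2 ratio of its markers to a baseline (the percentile 25 over clusters, pseudocount 20 CPM), with at least 3 markers detected in 20% of its cells and a score of at least 1. In addition, among its 10 top genes no other class may have more markers than its own, and a cluster with a median UMI total far below that of its libraries (under 1/3) needs a marker of its own there. Clusters named by the score alone, and an exact test on pairs of libraries within lanes for the shares, were added as alternatives after the data were seen. Cells are called X-like because names rest on transcripts alone. RNA free in the suspension was not removed.

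UMIs of AE2-like cells were summed per library (739 to 1419 cells and 4189868 to 12834450 UMIs), so that cells are not replicates. Genes were filtered with filterByExpr, which left 11359, scaled with TMM (factors 0.979 to 1.03; the 10 most abundant genes held 30.6% to 40.6% of the UMIs) and tested with the robust quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, all 8 libraries in 1 fit with group as the factor and 4 residual degrees of freedom (biological coefficient of variation 0.0877). Adjusted p-values are Benjamini-Hochberg over all genes tested, with a threshold of 0.05. The comparisons were LPS against control at each age, old against young in each treatment, and their interaction. Gene CPM are scaled with TMM and given as mean and SD of 2 libraries. Fold changes are log2 with an SE that is approximate. It was taken as the absolute log2 fold change over the square root of the F statistic of the quasi-likelihood test. Within-lane log2 ratios compare the 2 libraries of a lane.

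Before the data were examined, 23 gene lists were fixed: surfactant and lamellar body, fatty acid and phospholipid synthesis, cholesterol synthesis, fatty acid oxidation, nuclear oxidative phosphorylation, mitochondrial genome, cytosolic ribosomal proteins, chemokines and cytokines, acute phase and antimicrobial, interferon response, NF-kappaB and Toll-like receptor pathway, MHC class II, MHC class I, endoplasmic reticulum stress, immediate-early and heat shock, cell cycle, transitional alveolar epithelium, senescence, antioxidant and NRF2 targets, tight junctions and ion transport, glycolysis and hypoxia, proteasome, and sex-linked genes. The marker classes were AE2, AE1, club/secretory, ciliated, basal, neuroendocrine, alveolar macrophage, monocyte/macrophage, dendritic, neutrophil, T cell, NK cell, B cell, plasma cell, endothelial, fibroblast, smooth muscle/pericyte, mesothelial, erythroid, platelet and mast/basophil. Lists were tested against the other genes with camera in limma 3.58.1 (preset correlation 0.01, then estimated), adjusted over the 23 lists of a comparison. The designs, alternatives and the rule for named genes were fixed then too. The rule takes, per comparison, the 8 largest changes in each direction among called genes with at least 20 CPM and the same sign in both lanes, up to 3 called members per list (the most abundant member if none is called), the 10 interaction genes with the smallest p, the 2 most abundant markers of each other class and the sex-linked genes; not each gene it takes is printed, and genes with 3 or fewer control UMIs are given no fold. Shares of cell classes were compared with two-sided exact permutation tests, 4 libraries against 4 (70 splits, smallest p 0.0286), and carry 95% exact binomial (Clopper-Pearson) intervals.

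The libraries of a lane are paired by the labels. The design had no lane term, and a fit with lane as a block (3 residual degrees of freedom) was an alternative. The deviations of 3792 genes from their group means correlated between groups at -0.0447 to 0.0932 in 5 of 6 pairs of groups and at 0.339 for young LPS and old LPS. Within groups, the log2 CPM of the 2 libraries correlated over those genes at 0.986 to 0.995, and the squared difference over its counting variance was 4.96 per gene in young control, 13.3 in young LPS, 6.62 in old control and 74.5 in old LPS. That ratio also grows with the UMIs of a gene and a library, and old LPS had the most UMIs. It is therefore not a measure of spread alone. The fit shares 1 estimate of spread over the groups, so old LPS enters the spread used for comparisons without it. P-values of comparisons with old LPS may be too small for the same reason. Ddx3y, on the Y chromosome, lay at 35.6 to 51.1 CPM and Xist at 0.467 to 1.75 CPM over the 8 libraries. The alternatives were edgeR with RLE factors, DESeq2 1.42.0, no filter on low counts, every deposited barcode, at least 1000 genes and at most 10% mitochondrial UMIs, doublets kept, all cells of the sort, doubled clustering resolution, depth thinned to the smallest library, the lane block, each library left out and an estimated correlation. The model was tested on simulated data for LPS in the young. Of 50 genes changed by each fold, 34 were recovered at 1.5-fold, 47 at 2-fold and 50 at 4-fold, with 7 false calls among 11190 genes, and 0 of 20 unchanged lists were called. The simulated genes varied independently and with the same spread in all groups. It therefore does not cover lists of correlated genes (estimated correlation 0.659 for MHC class II) or a group with a larger spread, such as old LPS. Ciliated-like cells were fitted in the same way. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9 were used.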

Results

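Single cells from the lungs of young (3 months) and old (18 months) C57BL/6JRj mice were profiled 24 h after saline (control) or lipopolysaccharide (LPS, 2.5 mg/kg), a bacterial cell wall component used here to injure the lung. Cells positive for the epithelial surface protein EpCAM were sorted, and each of the 4 groups received its own hashtag antibody. The 4 groups were pooled on 1 lane of a droplet instrument, and the whole experiment was done on 2 lanes. This gave 8 libraries, 2 per group, and 14048 barcodes. The total counts of unique molecular identifiers (UMIs) were 6228266 and 9425267 in young control 1 and 2, and 9496168 and 10530570 in young LPS 1 and 2. In the old mice they were 8913881 and 10694651 in control 1 and 2, and 15435789 and 15164672 in LPS 1 and 2. After the filters, 11232 cells remained. Comparisons of genes rest, where no other class is named, on AE2-like cells, those with the transcriptome of alveolar epithelial type II cells, which make surfactant. Each library counts as 1 replicate. The labels do not say how many mice went into each library, so p-values measure only the spread between these libraries.

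AE2-like cells were 78.8% of the 11232 cells (8848 cells). Ciliated-like cells were 8.04%, dendritic-like cells 4.70%, alveolar macrophage-like cells 4.57% and club/secretory-like cells 1.66%. Monocyte/macrophage-like cells made up 0.418%, B cell-like cells 0.374% and neutrophil-like cells 0.267%. A cluster with high Mgl2 and Cd209a held 1.20%. Its highest marker score was for monocyte/macrophage, but it was left unnamed because its top genes held 0 markers of that class and 1 of another. AE2-like cells were 77.7% ± 6.70 (SD, n = 2) of the young control cells and 86.7% ± 3.66 after LPS. In the old they were 71.7% ± 0.458 and 79.7% ± 9.04. Over both ages the AE2-like share was 83.2% after LPS and 74.7% in controls (4 libraries each, two-sided exact permutation p = 0.0571, adjusted over 9 classes 0.129). Alveolar macrophage-like cells were 1.18% after LPS and 7.60% in controls (exact permutation p = 0.0286, the smallest that 70 splits can give, adjusted 0.0857). The difference of -6.42 points is -1.95 without old control 2. Monocyte/macrophage-like cells were 0.615% and 0.152%, and the unnamed cluster 0.116% and 2.55%, each with the same exact permutation p = 0.0286 and adjusted p = 0.0857. With the unnamed cluster counted as monocyte/macrophage-like, an alternative chosen after the data were seen, that class is 0.731% after LPS and 2.70% in controls (exact permutation p = 0.0571, adjusted 0.152), so its direction depends on the naming. The remaining classes were ciliated-like at 8.44% and 7.47% (exact permutation p = 0.800), club/secretory-like at 2.14% and 1.03% (exact permutation p = 0.171), and dendritic-like at 3.62% and 5.94% (exact permutation p = 0.200). Neutrophil-like cells were 0.343% and 0.151% (exact permutation p = 0.371) and B cell-like cells 0.352% and 0.408% (exact permutation p = 0.771). Between old and young mice the AE2-like share was 75.7% and 82.2% (exact permutation p = 0.314, adjusted 0.804), and 0.314 was the lowest p of the 9 classes. This test does not use the lanes. In the 4 pairs of libraries of a lane the AE2-like share was lower in the old each time, at 72.0% and 73.0%, 73.3% and 84.1%, 71.4% and 82.4%, and 86.1% and 89.3%. This depends on the filter: with every deposited barcode old control 1 has 62.9% and young control 1 has 50.6%, and the old minus young difference over all libraries is 2.76 points rather than -6.46. The neutrophil-like share was higher in the old in all 4 pairs (1 to 15 cells per library). After LPS the AE2-like, club/secretory-like and monocyte/macrophage-like shares were higher and the alveolar macrophage-like and unnamed shares lower in all 4 pairs. An exact test on such pairs, chosen after the data were seen, gives p = 0.125 for each, the smallest it can give. None of the shares passed after adjustment. The EpCAM sort shapes these shares, so they are not shares of lung cells.

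Within lanes, the alveolar macrophage-like share was higher in control than in LPS libraries at both ages. In the young it was 3.65% and 0.417% in lane 1 and 2.82% and 0.962% in lane 2. In the old it was 2.92% and 0.748% in lane 1. In lane 2 of the old it was 21.0% (321 of 1528 cells, 95% exact binomial interval 19.0% to 23.1%) and 2.61%. The ciliated-like share was lower in lane 2 than in lane 1 in each group. It was 4.05% and 11.4% in young controls, 4.73% and 7.67% in young LPS, 3.40% and 11.1% in old controls, and 6.13% and 15.2% in old LPS. Binomial intervals cover counting error only.

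**Figure D1:**
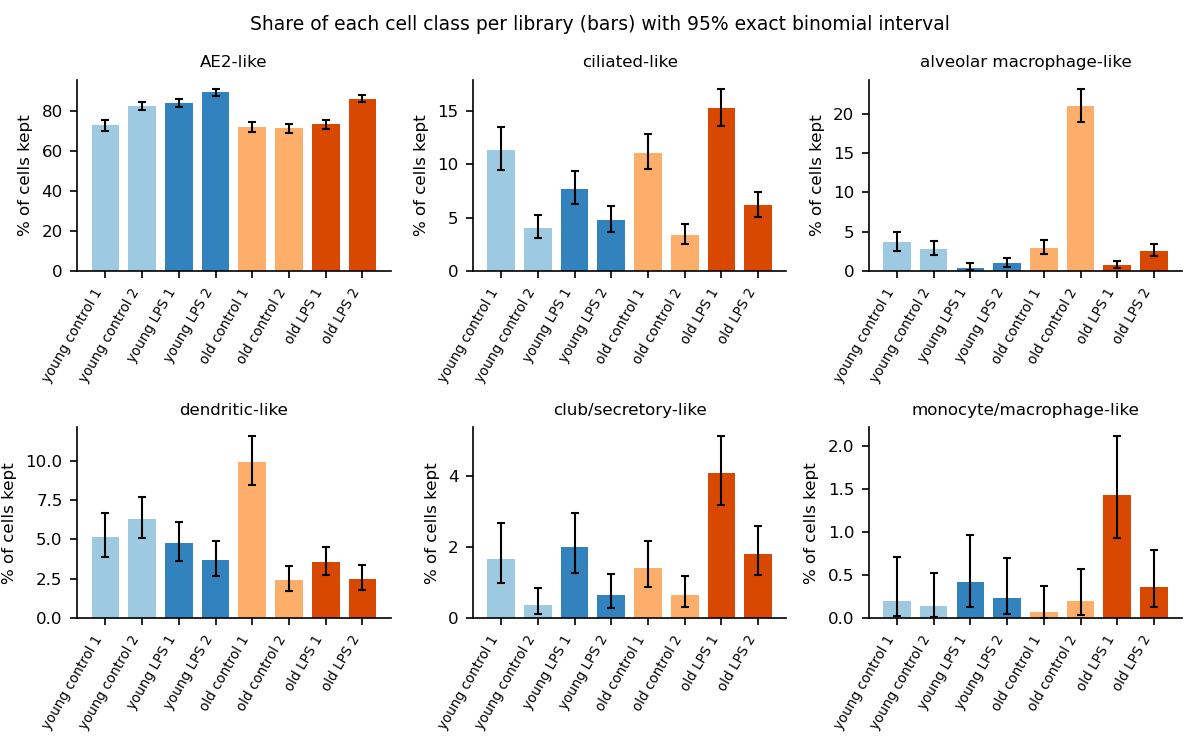
Share of 6 cell classes among the cells kept, in percent, for each of the 8 libraries, with bars as shares and error bars as 95% exact binomial intervals. The AE2-like share lies between 71.4% and 89.3%, and old control 2 holds 21.0% alveolar macrophage-like cells.

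AE2-like cells of control and LPS mice fell into separate clusters, 4 and 6 of them. Between 98.2% and 99.8% of the AE2-like cells of each library lay in the clusters of their own treatment. Among controls, cluster 1 (top genes Bex2 and S100g) held 29.5% and 24.2% of the AE2-like cells of the young libraries and 62.1% and 47.7% of the old. Cluster 3 (top gene Lyz1, lysozyme) held 36.4% and 36.8% of the young and 20.7% and 26.1% of the old, and clusters 6 and 13 the other control cells. After LPS, cluster 2, led by the interferon-induced GTPases Iigp1 and Gbp2, held 51.6% and 38.5% of the young AE2-like cells and 8.63% and 16.9% of the old. Cluster 4, led by the neutrophil chemokine Cxcl1, held 100 of 1009 and 84 of 1113 young cells but 637 of 1275 and 343 of 1419 old cells. Cluster 7 (Cxcl1, Saa3, Orm1) held 37 and 59 young cells and 361 and 231 old cells. Cluster 5 (Itih4, Rgcc) held 27.1% and 34.8% of the young and 7.53% and 16.1% of the old. Cluster 8 (Pmvk, Rgcc) held 40 and 107 young cells, 42 cells of old LPS 1 and 323 of old LPS 2 (22.8%), and its UMI totals were 0.737 of the median of the libraries. The 2 old LPS libraries thus differ in this cluster. Cluster 17 held the rest. Shares of 2 libraries against 2 allow too few splits for an exact permutation test to pass, so they were not tested.

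**Figure D2:**
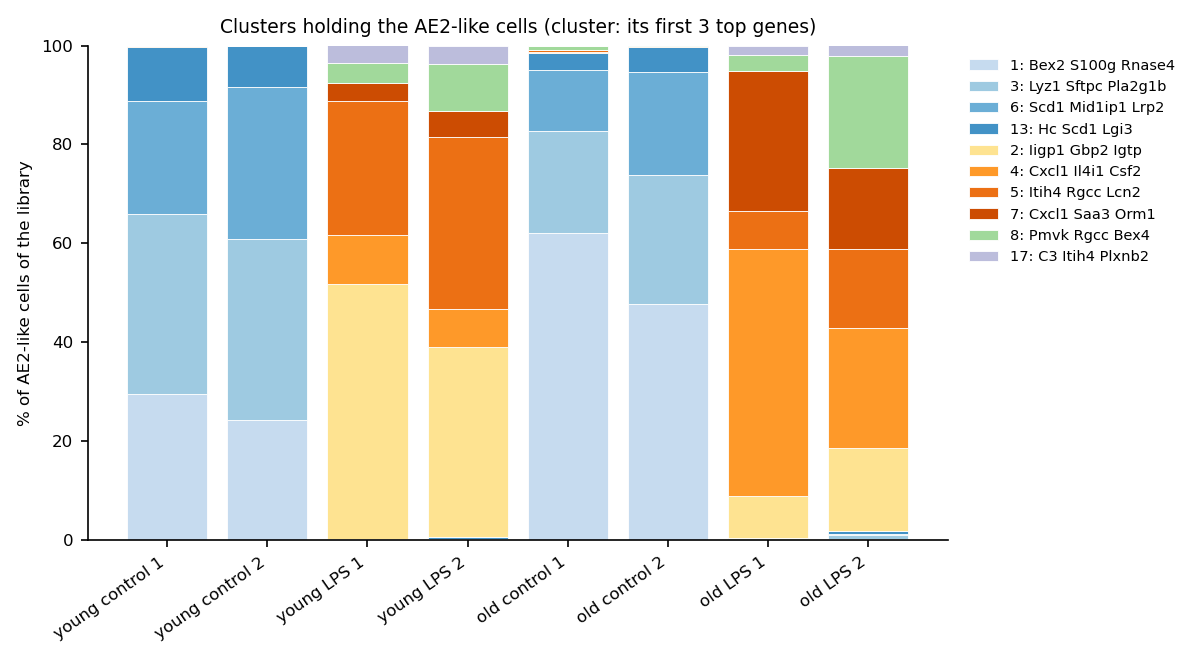
Clusters holding the AE2-like cells, as percent of the AE2-like cells of each of the 8 libraries, each colour a cluster named with its top genes. Cluster 2 takes 51.6% and 38.5% of the young LPS cells and 8.63% and 16.9% of the old LPS cells.

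Among the genes that LPS raised most in AE2-like cells of young mice were interferon-induced and acute phase genes, and this comparison asks what the injury does to these cells at 3 months. Orm1 encodes an acute phase plasma glycoprotein (ENSMUSG00000039196, chromosome 4, 63344560 to 63348163 on the plus strand of GRCm38, protein coding). It rose from 10.7 ± 1.10 to 2519.5 ± 484 CPM (counts scaled by library size, SD, n = 2 libraries), a log2 fold change of 7.85 ± 0.30 (SE, adjusted p = 1.86e-06, edgeR). Iigp1, an interferon-induced GTPase (ENSMUSG00000054072, chromosome 18, 60376027 to 60392634, plus strand), rose by 8.12 ± 0.60 to 955 ± 232 CPM. Gbp2, a guanylate-binding protein (ENSMUSG00000028270, chromosome 3, 142620602 to 142638008, plus strand), rose by 7.38 ± 0.26 to 869 ± 203 CPM. Among the genes that fell most were Nrep (-4.11 ± 0.31), Myh7, a cardiac myosin heavy chain (-3.17 ± 0.30), Tinag (-2.88 ± 0.27) and the transcription factor gene Sox4 (-2.83 ± 0.12, 79.5 ± 1.08 to 11.1 ± 1.40 CPM). Sftpc, the surfactant protein C gene and the most abundant transcript of these cells, fell from 246560.0 ± 17282 to 46652 ± 10246 CPM (-2.40 ± 0.20, adjusted p = 5.59e-05). Lcn2, an iron-sequestering antimicrobial protein, rose from 2332 ± 130.0 to 82275 ± 4535 CPM (5.14 ± 0.17). In the comparisons after LPS, Sftpc and Lcn2 were chosen for their abundance after their values were seen. The sums held 1009 and 1113 cells after LPS (7678951 and 9123387 UMIs) and 739 and 1140 control cells (4189868 and 7448654 UMIs). In all, 2498 of 11359 genes tested were higher and 2096 lower after LPS, 834 and 770 of them by over 2-fold. In the lanes taken alone, 2497 of the 2498 and all 2096 had the same sign in both. The calls rest on these same libraries, so a shared sign nearly follows from a call, here and in the other comparisons. The within-lane log2 ratio of Orm1 was 7.64 in lane 1 and 7.84 in lane 2. Without young control 2 the counts were 1662 and 1267, and without young LPS 1 the lower count was 1311.

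All 36 interferon response genes rose in the young. The interferon list had a median of 5.19 (camera adjusted p = 2.65e-26, and adjusted p = 0.141 with an estimated correlation). With 5 genes of 3 or fewer control UMIs set against that floor, the median is 4.62. They include Zbp1, a sensor of nucleic acids (6.17 ± 0.18), Usp18, which restrains type I interferon signalling (6.17 ± 0.21), and the transcription factor gene Irf7 (5.20 ± 0.21). All 18 MHC class I genes rose, among them the peptide transporter genes Tap1 (4.29 ± 0.15) and Tap2 (3.22 ± 0.12). The MHC class I list had a median of 2.84 (camera adjusted p = 9.17e-16, and adjusted p = 0.141 with an estimated correlation). Of 10 MHC class II genes 9 rose, such as H2-DMb1 (1.18 ± 0.11). The MHC class II list had a median of 1.21 (camera adjusted p = 6.56e-05, and adjusted p = 0.419 with an estimated correlation). Proteasome genes rose in 36 of 37 cases. The proteasome list had a median of 0.83 (camera adjusted p = 1.31e-13, and adjusted p = 0.367 with an estimated correlation). The immunoproteasome subunit Psmb8, also of the class I list, rose by 3.58 ± 0.12.

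Of 21 acute phase and antimicrobial genes 15 rose and 2 fell (15 and 3 adjusted over the list alone), with the protease inhibitor Slpi at 3.80 ± 0.12 and haptoglobin, Hp, at 3.23 ± 0.11. The acute phase list had a median of 3.104 (camera adjusted p = 5.51e-08, and adjusted p = 0.0785 with an estimated correlation). Among 20 chemokines and cytokines 16 rose and 2 fell. The chemokine list had a median of 2.95 (camera adjusted p = 3.68e-07, and adjusted p = 0.207 with an estimated correlation). Those that rose include Csf2, the macrophage growth factor GM-CSF (2.75 ± 0.19), Csf1 (3.29 ± 0.28) and Cxcl17 (1.89 ± 0.14). In the NF-kappaB and Toll-like receptor list 19 of 24 rose and 1 fell (21 and 1 adjusted over the list alone). The NF-kappaB list had a median of 1.80 (camera adjusted p = 7.32e-10, and adjusted p = 0.207 with an estimated correlation). Sod2, a mitochondrial superoxide dismutase (3.11 ± 0.12), and the adhesion molecule Icam1 (1.76 ± 0.10) are among them. Endoplasmic reticulum stress genes rose in 15 of 22 cases and fell in 0 (18 and 0 adjusted over the list alone). The reticulum stress list had a median of 0.64 (camera adjusted p = 3.91e-07, and adjusted p = 0.141 with an estimated correlation). The secreted chaperone Manf rose by 1.77 ± 0.10 and Sdf2l1 by 2.22 ± 0.13.

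Lipid and energy genes moved in different directions in the young. Of 22 fatty acid and phospholipid synthesis genes 14 fell and 2 rose (15 and 2 adjusted over the list alone). They include Acly, which makes cytosolic acetyl-CoA (-1.32 ± 0.13), and Srebf1, a transcription factor of lipid synthesis (-1.07 ± 0.13). The fatty acid synthesis list had a median of -0.50 (camera adjusted p = 1.79e-04, and adjusted p = 0.454 with an estimated correlation). Of 80 nuclear oxidative phosphorylation genes 58 rose and 2 fell (60 and 2 adjusted over the list alone), such as Atp5f1 (1.17 ± 0.09). The oxidative phosphorylation list had a median of 0.42 (camera adjusted p = 2.22e-09, and adjusted p = 0.207 with an estimated correlation). By contrast 8 of 13 mitochondrial genome transcripts fell, such as mt-Nd5 (-0.42 ± 0.09). The mitochondrial genome list had a median of -0.28 (camera adjusted p = 0.00841, and adjusted p = 0.488 with an estimated correlation). Without young LPS 1 this list had adjusted p = 0.0627. Antioxidant genes rose in 10 and fell in 3 of 21 cases (12 and 3 adjusted over the list alone), with the ferritin heavy chain gene Fth1 at 3.67 ± 0.12 and the peroxiredoxin Prdx6 at 1.91 ± 0.17. The antioxidant list had a median of 0.38 (camera adjusted p = 0.00709, and adjusted p = 0.454 with an estimated correlation). Of 16 genes of transitional alveolar epithelium, an injury-associated state, 5 rose and 1 fell, among them the cell cycle inhibitor Cdkn1a (1.99 ± 0.16) and clusterin, Clu (2.14 ± 0.16). The transitional epithelium list had a median of 0.17 (camera adjusted p = 0.0420, and adjusted p = 0.497 with an estimated correlation). That list had adjusted p = 0.111 without young control 1 and 0.0627 without young LPS 1.

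Surfactant and lamellar body genes did not pass as a list in the young (3 rose and 8 fell of 18, median -0.17, adjusted p = 0.187). Sftpd, a surfactant collectin, rose (1.39 ± 0.10), as did the protease gene Ctsh (1.43 ± 0.10), and Lpcat1, an enzyme of surfactant phospholipid, fell (-1.11 ± 0.10). Cholesterol synthesis (4 rose and 5 fell of 23, 7 and 6 adjusted over the list alone) had a median of 0.06 and a mean of -0.03, with adjusted p = 0.894. Fatty acid oxidation (7 and 2 of 20, 0.0579), cytosolic ribosomal proteins (12 and 4 of 80, 7 and 2 adjusted over the list alone, 0.548) and immediate-early and heat shock genes (8 and 2 of 19, 0.178) did not pass. Cell cycle genes (1 and 2 of 14, 1 and 1 adjusted over the list alone) had a median of 0.01 and a mean of -0.08 (0.746). Senescence (6 and 0 of 12, 0.0722) and tight junctions and ion transport (7 and 5 of 17, 0.279) did not pass either. Nor did glycolysis and hypoxia (9 and 4 of 18, 10 and 4 adjusted over the list alone, 0.0772) or sex-linked genes (1 and 1 of 5, 1 and 2 adjusted over the list alone, 0.287). None of the 13 lists called in the young passed with an estimated correlation.

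LPS in old mice also raised acute phase genes in AE2-like cells, and this comparison asks what the injury does at 18 months. Orm1 rose by 7.60 ± 0.29 (log2, SE) to 2667 ± 552 CPM (SD, n = 2 libraries, adjusted p = 1.51e-06, edgeR). Saa3, a serum amyloid A protein (ENSMUSG00000040026, chromosome 7, 46711998 to 46715700 on the minus strand), rose by 7.25 ± 0.18, from 72.7 ± 9.02 to 11050.0 ± 1709 CPM. Il4i1, a secreted amino acid oxidase, rose from 15.7 ± 1.87 to 1705 ± 385 CPM (6.77 ± 0.31) and Slfn2 by 6.75 ± 0.23. Genes that fell included Nrep (-3.27 ± 0.28), Cst8 (-3.27 ± 0.50) and Dgkg, a diacylglycerol kinase (-2.71 ± 0.17). Sftpc fell from 222360.0 ± 9867 to 58656 ± 13978 CPM (-1.92 ± 0.20, adjusted p = 1.39e-04) and Lcn2 rose from 2325 ± 116 to 76090.0 ± 19752 CPM (5.03 ± 0.17). The sums held 1275 and 1419 cells after LPS (11220525 and 12834450 UMIs) and 1062 and 1091 control cells (6213555 and 7807798 UMIs). In all, 2876 genes were higher and 2660 lower, 949 and 882 by over 2-fold. Each called gene had the same sign in both lanes, and the within-lane log2 ratio of Saa3 was 7.19 in lane 1 and 7.26 in lane 2. Without old control 2 the lower count was 1744.

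In the old too, all 36 interferon response genes rose, with Zbp1 at 5.16 ± 0.17 and Irf7 at 4.10 ± 0.19. The interferon list had a median of 4.10 (camera adjusted p = 4.20e-21, and adjusted p = 0.158 with an estimated correlation). With 6 genes set against the floor of 3 control UMIs the median is 3.93. All 18 MHC class I genes rose, as did 8 of 10 MHC class II genes and 36 of 37 proteasome genes. Tap1 rose by 2.81 ± 0.14 and Cd74, the class II invariant chain, by 0.87 ± 0.10. The MHC class I list had a median of 1.99 (camera adjusted p = 1.16e-11, and adjusted p = 0.158 with an estimated correlation). The MHC class II list had a median of 0.77 (camera adjusted p = 0.00470, and adjusted p = 0.458 with an estimated correlation). The proteasome list had a median of 0.89 (camera adjusted p = 3.02e-13, and adjusted p = 0.331 with an estimated correlation).

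Chemokines and cytokines of the old rose in 16 and fell in 1 of 20 cases, including Csf2 (3.81 ± 0.18) and Tnfsf9, a T cell costimulatory ligand (2.19 ± 0.13). The chemokine list had a median of 3.92 (camera adjusted p = 1.01e-08, and adjusted p = 0.158 with an estimated correlation). Acute phase and antimicrobial genes rose in 15 and fell in 3 of 21 cases, with Slpi at 4.23 ± 0.12. The acute phase list had a median of 3.65 (camera adjusted p = 8.31e-08, and adjusted p = 0.0846 with an estimated correlation). In the NF-kappaB and Toll-like receptor list 23 of 24 rose (23 and 1 lower adjusted over the list alone), such as Sod2 (3.46 ± 0.12) and Icam1 (2.23 ± 0.11). The NF-kappaB list had a median of 2.13 (camera adjusted p = 5.96e-13, and adjusted p = 0.158 with an estimated correlation). Endoplasmic reticulum stress genes rose in 18 and fell in 1 of 22 cases, with Sdf2l1 at 3.07 ± 0.13 and Manf at 2.22 ± 0.10. The reticulum stress list had a median of 0.80 (camera adjusted p = 8.31e-08, and adjusted p = 0.158 with an estimated correlation).

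Fatty acid and phospholipid synthesis genes of the old fell in 16 and rose in 2 of 22 cases (16 and 3 adjusted over the list alone), with Acly at -1.41 ± 0.13 and Srebf1 at -1.15 ± 0.12. The fatty acid synthesis list had a median of -0.81 (camera adjusted p = 5.48e-05, and adjusted p = 0.437 with an estimated correlation). Of 80 oxidative phosphorylation genes 52 rose and 3 fell (53 and 3 adjusted over the list alone), such as Atp5f1 (0.99 ± 0.09). The oxidative phosphorylation list had a median of 0.41 (camera adjusted p = 8.31e-08, and adjusted p = 0.207 with an estimated correlation). Mitochondrial genome transcripts fell in 10 of 13 cases. The mitochondrial genome list had a median of -0.41 (camera adjusted p = 0.00266, and adjusted p = 0.438 with an estimated correlation). Transitional alveolar epithelium genes rose in 9 and fell in 1 of 16 cases, with Clu at 3.44 ± 0.17 and the keratin Krt18 at 0.91 ± 0.10. The transitional epithelium list had a median of 1.02 (camera adjusted p = 0.00288, and adjusted p = 0.436 with an estimated correlation). With 2 genes at the floor its median is 0.94.

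Senescence genes rose in 7 and fell in 1 of 12 cases in the old, among them Mif, a cytokine (0.83 ± 0.10), and Trp53 (1.31 ± 0.19), which do not mark senescence alone. The senescence list had a median of 0.80 (camera adjusted p = 0.0129, and adjusted p = 0.438 with an estimated correlation). Antioxidant genes rose in 13 and fell in 2 of 21 cases, with Fth1 at 3.95 ± 0.13. The antioxidant list had a median of 0.47 (camera adjusted p = 0.00176, and adjusted p = 0.436 with an estimated correlation). Glycolysis and hypoxia genes rose in 9 and fell in 2 of 18 cases (10 and 2 adjusted over the list alone), with Hif1a, the oxygen-regulated transcription factor, at 1.54 ± 0.10. The glycolysis list had a median of 0.56 (camera adjusted p = 0.0166, and adjusted p = 0.288 with an estimated correlation). The other 8 lists did not pass. Surfactant and lamellar body genes (3 rose and 9 fell of 18) had a median of -0.33 and adjusted p = 0.0838, with Sftpd up by 1.64 ± 0.11. The rest were cholesterol synthesis (3 and 10 of 23, 0.101), fatty acid oxidation (10 and 1 of 20, 10 and 3 adjusted over the list alone, 0.144) and cytosolic ribosomal proteins (17 and 7 of 80, 12 and 6 adjusted over the list alone, 0.190). Immediate-early and heat shock (3 and 3 of 19, 0.870), cell cycle (6 and 1 of 14, 0.144), tight junctions and ion transport (7 and 4 of 17, 0.354) and sex-linked genes (0 and 2 of 5, 0.388) did not pass either. None of the 15 lists called in the old passed with an estimated correlation.

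Young and old AE2-like cells shared most of this response. The sets called in both ages held 2067 genes higher and 1654 lower, against 632 and 491 for independent sets, while 6 and 7 genes were called in opposite directions. Of the 6396 genes called at either age, 6079 had the same sign in both. The log2 fold changes correlated over all 11359 genes with r = 0.874, and genes are not independent replicates. The 2 comparisons use different libraries.

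**Figure D3:**
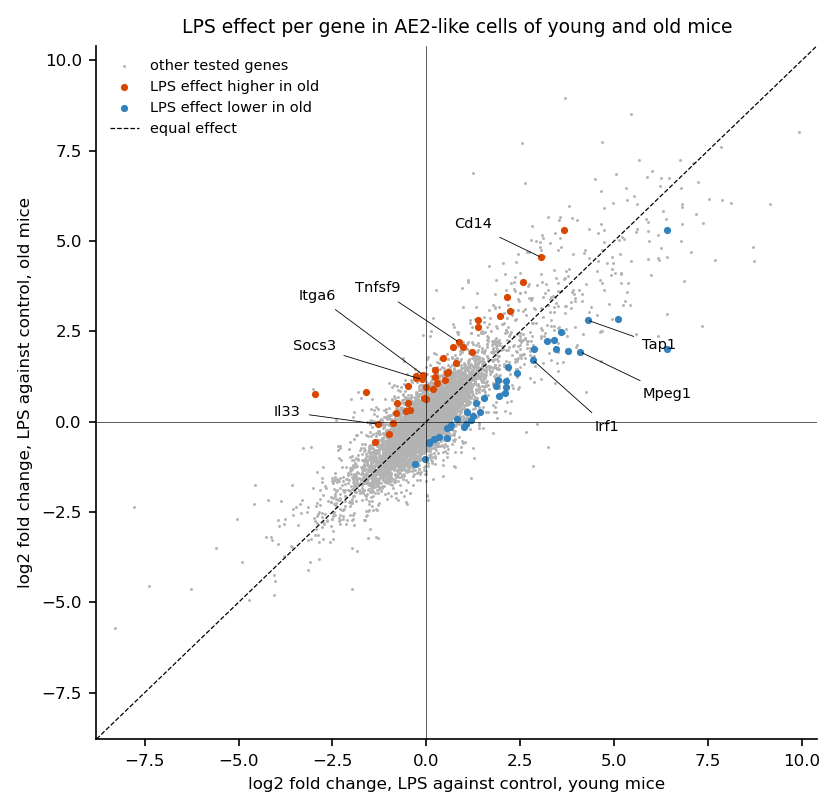
Log2 fold change after LPS in old (y axis) against young mice (x axis) for 11359 genes in AE2-like cells, 2 libraries per group, with the 79 genes whose LPS effect differed with age in colour and a dashed line at equal effects. Tap1 lies at 4.29 in the young and 2.81 in the old, and Cd14 at 3.06 and 4.55.

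Markers of other cell types within the AE2-like sums also moved with LPS. Of 6 club/secretory markers tested, 2 fell in the young and 3 in the old. Cyp2f2, a xenobiotic-metabolising enzyme, fell (-1.76 ± 0.26 and -1.70 ± 0.23). The secretoglobin Scgb1a1 fell from 1814 ± 183 to 753 ± 162 CPM in the young (-1.27 ± 0.30, adjusted p = 0.0257) and from 4364 ± 489 to 1959 ± 715 CPM in the old (-1.16 ± 0.30, adjusted p = 0.0287). The Scgb1a1 calls end with lane as a block (adjusted p = 0.0540 and 0.0561). In the young they end without young control 1 (0.0738), young LPS 1 (0.0913) or young control 2 (0.0517), and in the old without old control 1 (0.102) or 2 (0.0637). Ciliated markers fell in 3 of 7 cases in the young and 5 in the old, such as Sec14l3 (-2.50 ± 0.17 and -2.69 ± 0.16). AE1 markers rose in 3 and fell in 2 of 10 cases in the young and rose in 1 and fell in 4 in the old. Ager, of that list, did not pass in the young (-0.09 ± 0.10). The 1 basal marker tested rose at both ages, and so did 1 and 2 of 4 alveolar macrophage markers (Plet1 2.70 ± 0.23 in the young) and the 1 B cell marker (Cd79b 0.50 ± 0.11 in the young). Of 2 endothelial markers 1 fell and Pecam1 rose (1.84 ± 0.24 and 2.26 ± 0.22). Of 2 platelet markers the chemokine Pf4 rose (3.23 ± 0.12 and 3.22 ± 0.11), and the other fell in the old. Neutrophil markers rose in 0 and fell in 2 of 4 cases in the young and rose in 1 and fell in 1 in the old. The 1 monocyte/macrophage marker fell and the 1 plasma cell marker rose in the old, and the 1 neuroendocrine marker fell in the young. The 1 smooth muscle/pericyte marker was not called. Dendritic, T cell, NK cell, fibroblast, mesothelial, erythroid and mast/basophil lists had 0 members expressed highly enough to be tested. Of the 13 AE2 markers, 2 rose and 8 fell at each age. RNA free in the suspension enters such sums. Scgb1a1, 55.4% of the UMIs of club/secretory-like cells of young controls, was 0.177% of those of AE2-like cells in young controls and 0.442% in old controls.

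**Figure D4:**
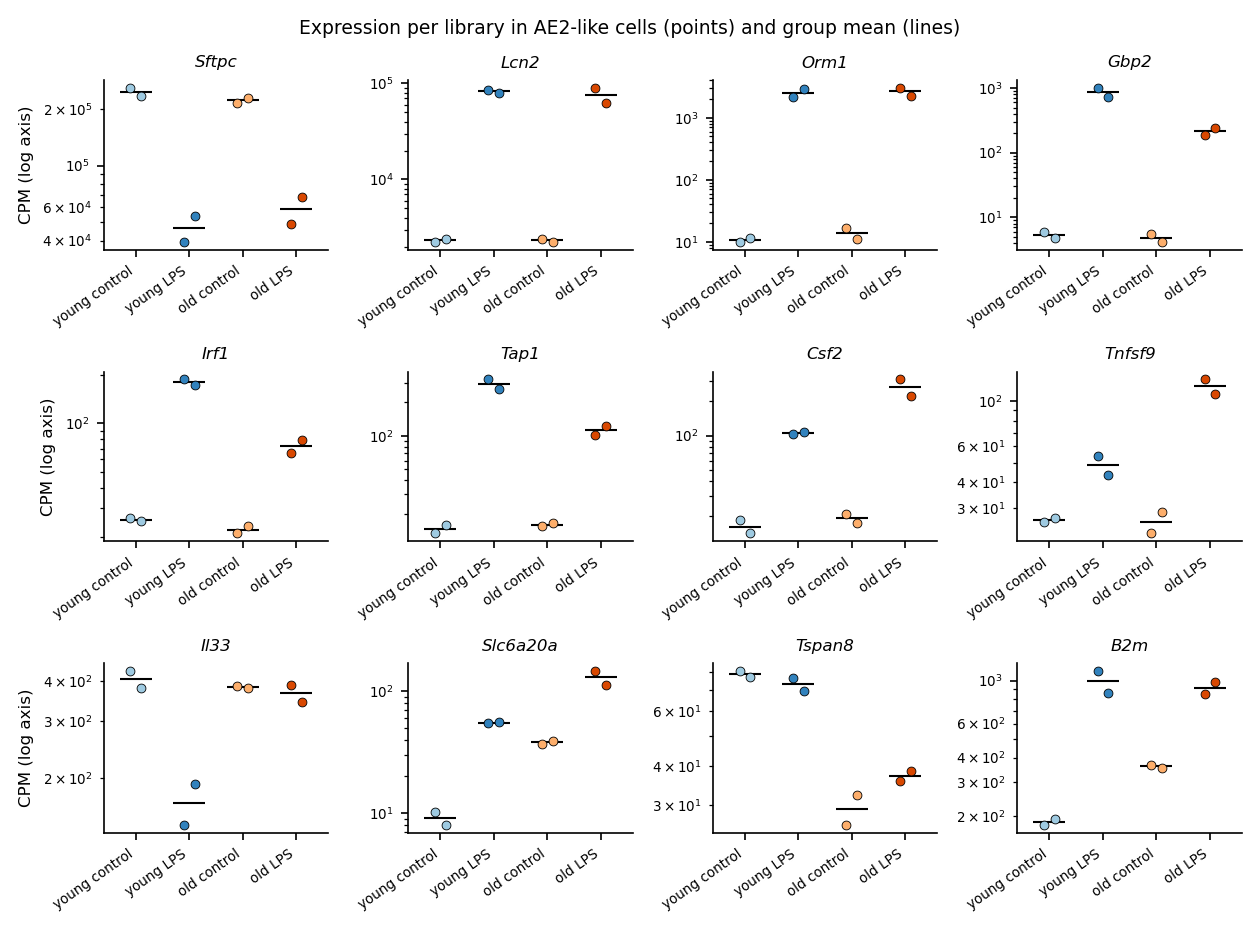
CPM (log axis) of 12 genes in the AE2-like sums of each library, with points for libraries and lines for means of 2 libraries. After LPS, Gbp2 averages 869 CPM in the young and 215 in the old, and Csf2 106 and 266.

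Few genes of AE2-like cells passed for age without injury, in the comparison of old against young control mice. Their number also rests on the LPS libraries, since all groups share 1 estimate of spread. The squared difference between libraries over its counting variance was 74.5 per gene in old LPS, against 4.96 in young and 6.62 in old control. Part of this gap can come from the larger UMI totals of old LPS, with which the ratio grows. Slc6a20a, a transporter of proline (ENSMUSG00000036814, chromosome 9, 123634770 to 123678885 on the minus strand), was higher in the old (38.0 ± 1.30 against 9.10 ± 1.53 CPM, SD, n = 2). Its log2 fold change was 2.10 ± 0.17 (SE, adjusted p = 8.69e-06, edgeR), and Macc1 was higher too (1.04 ± 0.11). Lower in the old were the tetraspanin Tspan8 (ENSMUSG00000034127, chromosome 10, 115816832 to 115849893, plus strand, -1.42 ± 0.12, adjusted p = 8.69e-06) and Itga6, the laminin-binding integrin alpha 6 (-1.59 ± 0.15). So were the kinase gene Pim1 (-1.16 ± 0.11) and Gadd45g, a stress-induced gene (-0.92 ± 0.10). In all 27 genes were higher and 42 lower in the old, 15 and 16 by over 2-fold, each with the same sign in both lanes (Slc6a20a 1.77 in lane 1 and 2.14 in lane 2). Leaving out 1 library moved these counts over 1.5-fold in 6 of 8 cases. They were 5 and 21 without young control 1, 2 and 6 without young control 2, 6 and 5 without old control 1, and 12 and 11 without old control 2. Without old LPS 1 they were 134 and 167, and without old LPS 2 they were 133 and 166. The 6 genes just named kept their calls in each of these. They are not typical, since most of the 22 called genes that the naming rule took lost their call without a single library.

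MHC class I genes were higher in old controls in 5 of 18 cases (7 adjusted over the list alone). The MHC class I list had a median of 0.30 (camera adjusted p = 2.05e-06, and adjusted p = 0.899 with an estimated correlation). B2m, the MHC class I light chain, was at 362 ± 9.38 against 186 ± 9.18 CPM (0.95 ± 0.12), and was not called without young control 1 (0.0571) or 2 (0.0821). H2-K1 (0.60 ± 0.10) was not called without young control 1 (0.271), young control 2 (0.2802), old control 1 (0.153) or old control 2 (0.259). H2-Q7 (2.05 ± 0.25) was not called without young control 1, young control 2, old LPS 1 or old LPS 2 (0.121, 0.2802, 0.149 and 0.1497), and H2-Q6 (1.60 ± 0.24) without old control 1 (0.0882) or young control 2 (0.318). H2-Q6 and H2-Q7 are close paralogs whose reads can be shared. NF-kappaB and Toll-like receptor genes were lower in 5 and higher in 0 of 24 cases (8 and 1 adjusted over the list alone). The NF-kappaB list had a median of -0.23 (camera adjusted p = 0.00544, and adjusted p = 0.899 with an estimated correlation). They include Socs3, a feedback inhibitor of cytokine signalling (-0.89 ± 0.12, adjusted p = 0.0608 without old control 1). Bcl3 (-0.90 ± 0.15) was not called without young control 1 (0.103), old control 1 (0.2535) or young control 2 (0.249). Cytosolic ribosomal proteins passed as a list with 0 of 80 members called by edgeR. The ribosomal list had a median of 0.11 (camera adjusted p = 6.36e-04, and adjusted p = 0.899 with an estimated correlation). Immediate-early and heat shock genes, which tissue dissociation induces, passed with 1 of 19 higher (3 adjusted over the list alone). The immediate-early list had a median of 0.26 (camera adjusted p = 0.0158, and adjusted p = 0.899 with an estimated correlation). Without old control 1 the ribosomal and NF-kappaB lists had adjusted p = 0.0591 and the immediate-early list 0.502, and without young control 2 the NF-kappaB and immediate-early lists had 0.0630.

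Surfactant genes, antioxidant genes and chemokines each had 1 member lower in old controls and did not pass as lists. Sftpd (-0.51 ± 0.10) was not called without old control 1 (0.547), young control 2 (0.607), old control 2 (0.123), or young LPS 1 or 2 (0.0642 each). Hmox1, the heme oxygenase (-0.66 ± 0.10), was not called without old control 1 (0.199), young control 2 (0.251) or old control 2 (0.0531), and Cxcl17 (-0.82 ± 0.15) without the same 3 (0.372, 0.517 and 0.105). The interferon list had 0 members called in controls (median -0.04 and mean 0.03, or a median of -0.12 with genes at the floor, adjusted p = 0.877), and the other 15 lists 0 too (2 lower in the transitional list adjusted over it alone). Over all genes edgeR gave 1161 at an unadjusted p under 0.05, and DESeq2 called 16 higher and 27 lower. The median and mean differed in sign for fatty acid synthesis (-0.03 and 0.02), acute phase (-0.07 and 0.03), senescence (-0.14 and 0.17), the proteasome (-0.00 and 0.02), cholesterol synthesis (0.00 and -0.04) and antioxidant genes (-0.04 and 0.00), none of which passed. Scgb1a1 was at 4364 ± 489 CPM in old and 1814 ± 183 in young controls (1.27 ± 0.30, adjusted p = 0.261). Of the marker lists, AE2 had 1 member lower and the other 20 had 0 called.

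After LPS, 20 of 36 interferon genes were lower and 7 of 20 chemokine and cytokine genes higher (1 lower) in old than in young AE2-like cells. Both lists pass camera with the preset correlation but have adjusted p = 0.559 with an estimated correlation. Irf1, a transcription factor of interferon responses (ENSMUSG00000018899, chromosome 11, 53770014 to 53778374 on the plus strand), was at 72.5 ± 9.05 against 181 ± 9.68 CPM (SD, n = 2). Its log2 fold change was -1.32 ± 0.10 (SE, adjusted p = 1.76e-06, edgeR). Irgm1, an interferon-induced GTPase, was lower by -1.70 ± 0.14 and Gbp2 by -2.01 ± 0.18 (215 ± 38.4 against 869 ± 203 CPM). Csf2 (ENSMUSG00000018916, chromosome 11, 54247271 to 54249667 on the minus strand) was higher in the old (266 ± 61.4 against 106 ± 3.46 CPM, 1.33 ± 0.15, adjusted p = 6.58e-04). So were the neutrophil growth factor gene Csf3 (107 ± 27.8 against 19.1 ± 5.54 CPM, 2.47 ± 0.27), Tnfsf9 (1.28 ± 0.12) and the alarmin Il33 (367 ± 31.4 against 167 ± 34.5 CPM, 1.14 ± 0.12). In all 200 genes were higher and 279 lower in the old, 64 and 67 by over 2-fold, each with the same sign in both lanes. Irf1 had -1.49 in lane 1 and -1.13 in lane 2, and Csf2 1.57 in lane 1 and 1.04 in lane 2. Leaving out 1 library moved the higher count over 1.5-fold each time but for old LPS 1. It was 122 without young control 1, 121 without young control 2, 88 without young LPS 1, 36 without young LPS 2, 119 without old control 1, 114 without old control 2 and 785 without old LPS 2. The lower count was 111 without young LPS 1, 137 without young LPS 2 and 960 without old LPS 2. The 7 genes just named kept their calls in each of these, while most of the 48 called genes that the naming rule took lost theirs without a single library. Of the genes higher in old controls, 6 were higher after LPS too and 2 lower, and of those lower in old controls, 11 were lower after LPS and 6 higher. Independent sets would hold 0.475 higher in both, 1.03 lower in both, 0.663 higher then lower and 0.7395 lower then higher, so both the same and the opposite direction exceed them.

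Of 36 interferon response genes 20 were lower in the old after LPS and 0 higher (28 and 0 adjusted over the list alone), with Igtp at -2.04 ± 0.22 and Usp18 at -1.42 ± 0.11. The interferon list had a median of -0.89 (camera adjusted p = 1.15e-18, and adjusted p = 0.559 with an estimated correlation). Socs1, a feedback inhibitor of interferon signalling, was lower too (-2.14 ± 0.31). MHC class I genes were lower in 12 of 18 cases (13 adjusted over the list alone), among them Tap1 (-1.38 ± 0.12), Tap2 (-0.72 ± 0.10) and Psmb8 (-0.84 ± 0.11). The MHC class I list had a median of -0.47 (camera adjusted p = 7.26e-08, and adjusted p = 0.559 with an estimated correlation). MHC class II genes were lower in 2 of 10 cases, including the class II transactivator Ciita (29.2 ± 6.79 against 65.8 ± 10.4 CPM, -1.16 ± 0.17). The MHC class II list had a median of -0.26 (camera adjusted p = 0.00891, and adjusted p = 0.559 with an estimated correlation). Its adjusted p was 0.423 without young LPS 1 and 0.0952 without old LPS 1. Chemokines and cytokines were higher in 7 and lower in 1 of 20 cases (10 and 2 adjusted over the list alone). The chemokine list had a median of 0.80 (camera adjusted p = 1.10e-05, and adjusted p = 0.559 with an estimated correlation). Cxcl1 (1.27 ± 0.22) was not called without old control 1 (0.0521), old control 2 (0.0554), old LPS 1 (0.241) or old LPS 2 (0.1001).

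In the NF-kappaB and Toll-like receptor list 2 of 24 were higher in the old after LPS (6 adjusted over the list alone), such as Cd14, the LPS coreceptor (0.69 ± 0.14, adjusted p = 0.141 without young LPS 2). The NF-kappaB list had a median of 0.24 (camera adjusted p = 8.71e-04, and adjusted p = 0.559 with an estimated correlation). Without old LPS 1, and without young LPS 2, its adjusted p was 0.105. Cholesterol synthesis genes were lower in 2 of 23 cases (4 adjusted over the list alone), such as Lss (-0.62 ± 0.14, adjusted p = 0.352 without young LPS 2). The cholesterol list had a median of -0.25 (camera adjusted p = 3.95e-05, and adjusted p = 0.559 with an estimated correlation). Ribosomal proteins passed with 1 of 80 members higher (0 adjusted over the list alone), and cell cycle genes with 1 of 14. The ribosomal list had a median of 0.14 (camera adjusted p = 1.90e-06, and adjusted p = 0.559 with an estimated correlation). The cell cycle list had a median of 0.34 (camera adjusted p = 0.00167, and adjusted p = 0.559 with an estimated correlation). Without old LPS 1 the cell cycle list had adjusted p = 0.210. Cdkn1a was lower in the old (-0.87 ± 0.15, adjusted p = 0.0666 without young LPS 1), and the complement gene Cfb higher (0.97 ± 0.14).

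The other 15 lists did not pass for age after LPS. Surfactant genes had 0 called (adjusted p = 0.0560), fatty acid synthesis 0 (0.0514), oxidative phosphorylation 0 (0.0610), and fatty acid oxidation 1 lower (2 adjusted over the list alone, 0.0884). Endoplasmic reticulum stress had 3 higher (4 adjusted over the list alone, 0.0610), transitional epithelium 2 higher and 1 lower (3 and 1 adjusted over the list alone, 0.0560) and acute phase 1 and 1 (2 and 1 adjusted over the list alone, 0.457). Senescence had 2 and 2 (3 and 3 adjusted over the list alone), tight junctions 1 and 1 (1 and 2), glycolysis 1 and 1 (3 and 2), antioxidant 1 higher, the proteasome 3 lower and the rest 0 called (immediate-early 1 and 1 adjusted over the list alone). Over all genes edgeR gave 1961 at an unadjusted p under 0.05. With lane as a block the surfactant and fatty acid synthesis lists pass (adjusted p = 0.0459 for each, and adjusted p = 0.559 and 0.614 with an estimated correlation and no block). Immediate-early genes had a median of -0.02 and a mean of 0.08. Of the marker lists, AE1 had 2 members lower, alveolar macrophage 1 lower and platelet 1 higher (Pf4 0.50 ± 0.09, adjusted p = 0.0799 without young LPS 1), and the others 0. Scgb1a1 was at 1959 ± 715 against 753 ± 162 CPM (1.38 ± 0.30, adjusted p = 0.0996).

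**Figure D5:**
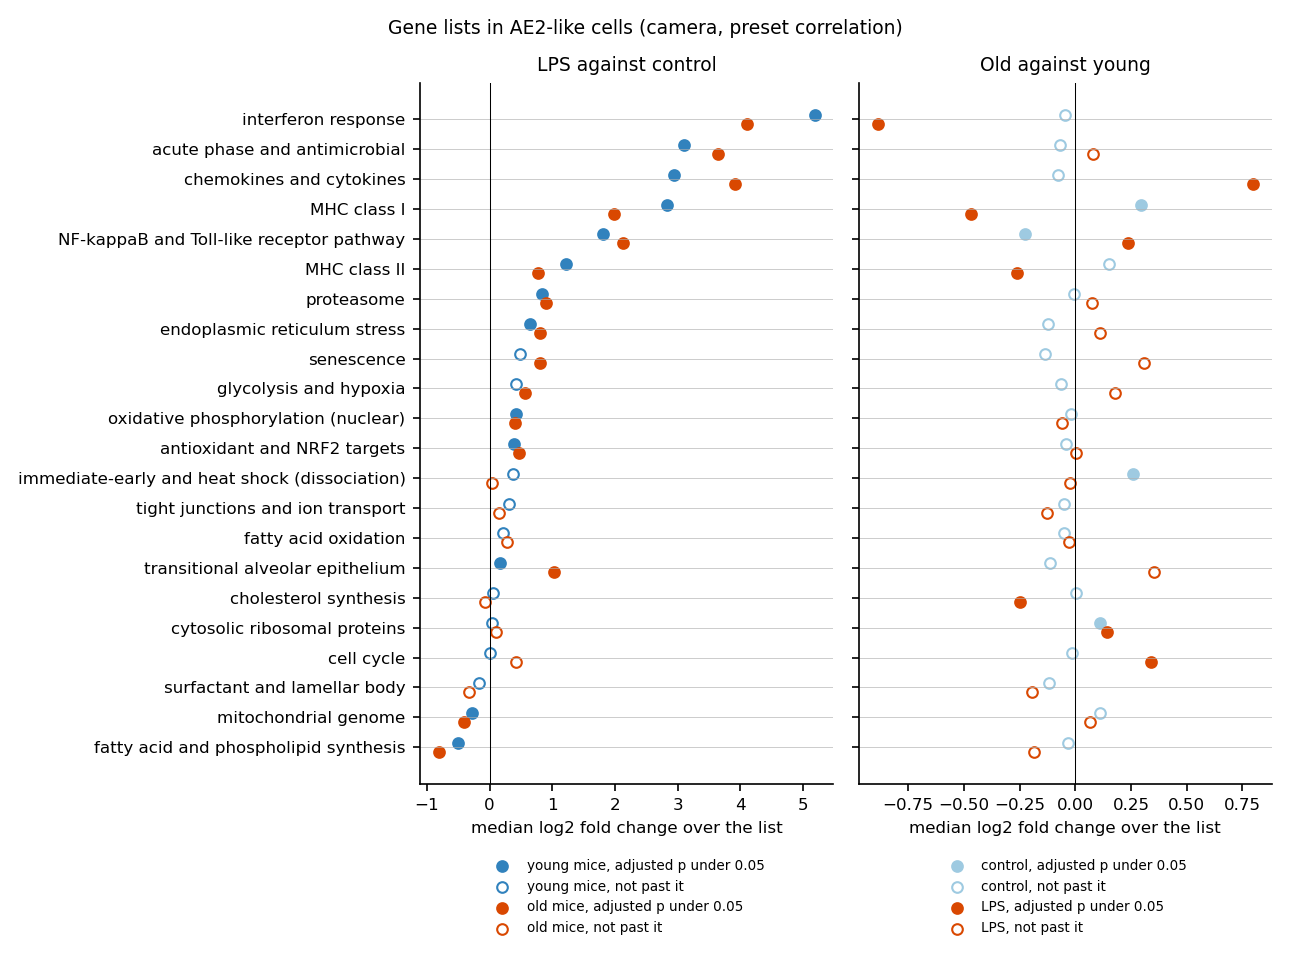
Median log2 fold change of 22 gene lists in AE2-like cells, after LPS at each age (left) and for old against young in control and LPS mice (right), filled where camera passed with the preset correlation (0 passed with an estimated correlation). The interferon list has medians of 5.19 and 4.10 after LPS in young and old mice and -0.89 for old against young after LPS.

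The interaction takes the LPS effect in the old minus that in the young (log2, SE), and so asks directly whether the response differs with age. Tap1 rose less in the old (-1.49 ± 0.21, adjusted p = 0.00295, edgeR, n = 2 libraries per group). Mpeg1, a pore-forming protein against bacteria, had a lower effect too (-2.16 ± 0.26), with 69.5 ± 8.22 CPM in the young and 24.0 ± 1.36 in the old after LPS. Cd14 rose more in the old (1.48 ± 0.20). Socs3 (1.29 ± 0.16) had 85.3 ± 13.5 CPM in control and 77.7 ± 1.57 in LPS libraries of the young, and 45.4 ± 1.46 and 102 ± 6.15 in the old. Bhlhe40, a transcription factor (1.47 ± 0.19), and Itga6 (1.38 ± 0.19) also had a higher effect in the old. A difference between old and young controls enters this value. Itga6 was lower in old than in young controls, so its higher effect does not show a higher level after LPS. In all 40 genes had a higher and 39 a lower LPS effect in the old, 21 and 20 by over 2-fold. The 6 genes just named kept their calls without each single library. Most of the 24 called genes that the naming rule took lost theirs in this way. Without young control 1 the counts were 16 and 10, without young control 2 they were 7 and 2, without old control 1 they were 6 and 5, and without old control 2 they were 20 and 15. Without old LPS 1 they were 73 and 90, and without old LPS 2 they were 333 and 473. Without young LPS 1 the lower count was 20, and without young LPS 2 the higher was 22.

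By list, the LPS effect was lower in the old for MHC class I (9 of 18 genes, 16 adjusted over the list alone) and the interferon response (2 of 36, 13 adjusted over the list alone). The MHC class I list had a median of -0.9995 (camera adjusted p = 1.46e-16, and adjusted p = 0.414 with an estimated correlation). Controls contribute to it, since its median for old against young was 0.30 in controls and -0.47 after LPS. The interferon list had a median of -0.98 (camera adjusted p = 6.15e-16, and adjusted p = 0.414 with an estimated correlation). The 2 interferon genes were Irf1 (-1.12 ± 0.17), not called without young control 2 (0.117) or old control 2 (0.0550), and Irgm1 (-1.44 ± 0.24), not called without young control 1 (0.117), young control 2 (0.227) or old control 2 (0.111). The effect was also lower for MHC class II (0 of 10, 2 adjusted over the list alone) and cholesterol synthesis (1 of 23, 2 adjusted over the list alone). The MHC class II list had a median of -0.50 (camera adjusted p = 4.90e-04, and adjusted p = 0.572 with an estimated correlation). The cholesterol list had a median of -0.23 (camera adjusted p = 0.00552, and adjusted p = 0.620 with an estimated correlation). The cholesterol list had adjusted p = 0.0852 without old LPS 1 and 0.138 without young LPS 2.

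A higher effect in the old was found for chemokines and cytokines (2 of 20, 3 adjusted over the list alone), with Il33 (1.21 ± 0.18, adjusted p = 0.0520 without old control 1) and Tnfsf9 (1.31 ± 0.20, not called without old control 1, 0.0517, or young control 2, 0.138). The chemokine list had a median of 1.11 (camera adjusted p = 8.42e-06, and adjusted p = 0.524 with an estimated correlation). In the NF-kappaB and Toll-like receptor list 5 of 24 were higher (8 higher and 1 lower adjusted over the list alone). The NF-kappaB list had a median of 0.45 (camera adjusted p = 2.90e-06, and adjusted p = 0.524 with an estimated correlation). Controls contribute here too, since its median for old against young was -0.23 in controls and 0.24 after LPS. Endoplasmic reticulum stress had 1 of 22 higher (5 adjusted over the list alone), transitional epithelium 2 of 16 (2 higher and 1 lower adjusted over the list alone) and cell cycle 0 of 14. The reticulum stress list had a median of 0.18 (camera adjusted p = 0.00721, and adjusted p = 0.524 with an estimated correlation). The transitional epithelium list had a median of 0.70 (camera adjusted p = 0.0261, and adjusted p = 0.620 with an estimated correlation). The cell cycle list had a median of 0.41 (camera adjusted p = 0.00341, and adjusted p = 0.568 with an estimated correlation). The transitional list had adjusted p = 0.129 without old control 1, 0.346 without old LPS 1, 0.276 without young control 2 and 0.0737 without young LPS 2. Clu, of that list, is called without a block (1.30 ± 0.22, adjusted p = 0.0372) and not with lane as a block (adjusted p = 0.153). The other 14 lists did not pass, with 1 gene higher in the acute phase and antioxidant lists and 2 lower in the proteasome list. Adjusted over the list alone, glycolysis and hypoxia had 4 higher, immediate-early 1 higher and 3 lower, senescence 1 higher and 2 lower, acute phase 1 and 1, and antioxidant 2 higher. Beside the counts of 0, edgeR gave 1148 genes at an unadjusted p under 0.05 over all genes, DESeq2 called 34 higher and 32 lower, and all 21 marker lists had 0 called. Antioxidant (median -0.01, mean 0.00), proteasome (0.03 and -0.02) and sex-linked genes (-0.15 and 0.19) had a median and mean of different sign.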

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

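Of the tests weighed here, those of fewer responding cells, of immune RNA, of free AE2 RNA and of UMI totals for the MHC class I and chemokine genes were chosen only after the result was seen; the tests of UMI totals for the interferon genes and of ciliated-like cells were chosen before.

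The LPS effect differed with age by the interaction test in 79 genes and 9 lists, and values are the log2 effect in the old minus that in the young. The 10 genes with the smallest p were Mpeg1 (-2.16), Socs3 (1.29), Rhou (1.42), Spink5 (-1.31), Bhlhe40 (1.47), Itga6 (1.38), Tap1 (-1.49), Adora2b (1.00), Hsp90ab1 (1.07) and Psmb8 (-1.10). Left-out libraries end the calls of Rhou and Spink5 (young control 2; adjusted p = 0.0708 and 0.0708), Adora2b and Hsp90ab1 (old control 1; 0.0512 and 0.0512) and Psmb8 (old control 1 or young control 2; up to 0.113). The list medians were MHC class I -0.9995, interferon response -0.98, MHC class II -0.50 and cholesterol synthesis -0.23, and chemokines and cytokines 1.11, transitional alveolar epithelium 0.70, NF-kappaB and Toll-like receptor pathway 0.45, cell cycle 0.41 and endoplasmic reticulum stress 0.18. With an estimated correlation 0 of the 9 lists passed, and transitional epithelium and cholesterol synthesis each lost their call without single libraries: transitional epithelium had adjusted p = 0.129 without old control 1, 0.346 without old LPS 1, 0.276 without young control 2 and 0.0737 without young LPS 2, and cholesterol synthesis 0.0852 without old LPS 1 and 0.138 without young LPS 2.

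After LPS, 20 of 36 interferon and 12 of 18 MHC class I genes were lower and 7 of 20 chemokine and cytokine genes higher (1 lower) in old than in young AE2-like cells, with adjusted p = 0.559 for each list with an estimated correlation. Fewer responding cells in the old would lower all induced genes, but the 34 acute phase and NF-kappaB genes raised at both ages had a median old against young difference of 0.21 (quartiles 0.06 and 0.37, 8 of 34 below 0), against -0.89 for 36 interferon genes. Thinned to the same UMI total per library, which leaves cells and UMIs per cell unequal, 100% of the interferon genes called lower (20 of 20) stayed below -0.3, and 18 stayed called, as did 10 of 12 MHC class I genes (12 below -0.3) and 7 of 7 chemokine and cytokine genes (7 above 0.3). Random thinning leaves the expected ratio of a gene unchanged, so the ratios could hardly have moved past these limits. The thinned values therefore do not decide whether UMI totals play a part. Interferon RNA from immune cells among the young AE2-like cells would need a median immune share of 18.0% (lowest 5.63%), while the marker of each class that allows least permits at most 0.0387% (Cd79a, B cell-like) and 0.0261% for alveolar macrophage-like cells (Marco). A difference with age in these cells therefore remains a hypothesis for the interferon genes, which the number of mice behind each library leaves open, and the MHC class I and chemokine parts were not tested for immune RNA.

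In ciliated-like cells of the same libraries the interferon genes were lower in the old too, with a median of -1.72 over 32 genes (20 called lower; camera adjusted p = 6.36e-26, and adjusted p = 0.204 with an estimated correlation). A candidate explanation is therefore an interferon signal that differed between the old and young LPS libraries as a whole rather than in AE2-like cells alone. Free AE2 RNA, if it brought all the Sftpc of these cells, would be 54.8 of the 390.0 CPM of Gbp2 in young LPS libraries. The median stays at -1.72 with it taken off. This estimate takes free RNA to come from AE2-like cells of the same group. The 4 groups of a lane were pooled, so free RNA shared between groups is not covered. Fewer responding ciliated-like cells in the old would lower all induced genes, but 19 acute phase and NF-kappaB genes raised at both ages had a median old against young difference of 0.14 (quartiles -0.02 and 0.22, 6 of 19 below 0, and 0.25 with free AE2 RNA taken off), against -1.83 for 15 interferon genes. Cluster 9, which held most control ciliated-like cells, had 26 of 265 and 31 of 101 old LPS cells. It had 6 of 92 and 10 of 59 young LPS cells. This share was higher in the old in each lane, so fewer responding cells may still add to the difference. The difference may follow age or the mice used, which this design cannot separate.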

How the results depend on the processing

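Leaving out the 3% of cells with the highest doublet scores, pairs within lanes and clusters named by score alone were chosen only after the data were seen; the other alternatives were planned. Over 19 alternatives per gene count, RLE factors, the looser and stricter cell filters, doublets kept, doubled resolution, the 3% left out and the lane block kept each count of genes within 1.5-fold, and among the named genes 4946 values kept direction and call, 456 lost the call and 9 reversed. Of the lists' values 510 held, 76 lost the call and 2 reversed. Where no reason is given the cause was not tested.

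DESeq2 called 1301 genes lower after LPS in the young, 1659 in the old, 16 higher and 27 lower in old controls, and 78 and 135 in old LPS mice. With no filter on low counts, 18066 genes were tested and called 117 and 131 (age, control), 440 and 449 (age, LPS) and 148 and 154 (interaction). With all cells of the sort, which adds other cell types by construction, the counts were 1138 lower after LPS in the young, 1755 and 1443 in the old, 1 and 0 for age in controls, 3 and 2 for age after LPS and 0 and 0 for the interaction (edgeR; unadjusted p under 0.05: 798, 1113 and 685), and 2 lists for age in controls. Thinned libraries gave 121 genes higher in old LPS mice, with fewer counts. An estimated correlation left 0 lists in each comparison. With every deposited barcode the old minus young difference was 2.76 for the AE2-like and 0.196 for the dendritic-like share (-6.46 and -0.371 with the filters). With all cells MHC class II reversed (adjusted p = 0.959 young, 0.248 old), as did H2-Eb1 (-0.60 young, -0.59 old), Scgb1a1 (0.14 young, 1.23 old) and, in the old, Tppp3 (0.16), Cenpa (-1.65), Dynlrb2 (0.14) and Plet1 (-0.32); with the stricter filter S100a9 in the old was -1.82.

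Without single libraries, where a lone library is assumed to vary like the other groups, genes higher and lower ranged over 1662 to 2846 and 1267 to 2479 (LPS, young; lowest without young control 2), 1744 to 2865 lower (LPS, old; lowest without old control 2), 2 to 134 and 5 to 167 (age, control; lowest without young control 2 and old control 1, highest without old LPS 1), 36 to 785 and 111 to 960 (age, LPS; lowest without young LPS 2 and young LPS 1, highest without old LPS 2) and 6 to 333 and 2 to 473 (interaction; lowest without old control 1 and young control 2, highest without old LPS 2). Called lists ranged over 1 to 4, 7 to 14 and 8 to 15 in the last 3. Share differences that changed sign were B cell-like after LPS (-0.169 to 0.0411) and with age (-0.199 to 0.0111), ciliated-like (-1.29 to 2.27 and -0.0865 to 3.86), dendritic-like with age (-2.14 to 0.354) and monocyte/macrophage-like with age (-0.0404 to 0.416). With clusters named by score alone the monocyte/macrophage-like difference reversed, to -1.97 after LPS and -0.971 with age, since the unnamed cluster joins that class by construction. Leaving out a whole lane leaves 0 residual degrees of freedom, so it gives no test. The lane block ended the calls of Clu (interaction, adjusted p = 0.153), Scgb1a1 (0.0540 and 0.0561 after LPS), Gbp3 (0.0878) and H2-DMa (0.0583) for age after LPS, and added the surfactant and fatty acid synthesis lists for age after LPS (0.0459 each, and 0.559 and 0.614 with an estimated correlation and no block). The lane block changed no other call of a named gene or list. With 2 libraries per group, 1.5-fold changes simulated for LPS in the young were recovered in 34 of 50 genes, which limits the absence of a call for small changes. Recovery for the age comparisons and the interaction is not given here and cannot be read from this value.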

Other observations

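The tests of the alveolar macrophage-like share in this part and the estimate of free AE2 RNA were chosen only after the result was seen, and the fits in ciliated-like cells were not planned as comparisons of their own.

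Ciliated-like cells responded to LPS as well (7902 genes tested with edgeR on 903 cells, 2 libraries per group of 52 to 265 cells each). The class splits by treatment, with 114, 55, 161 and 50 control cells in cluster 9 (1, 1, 2 and 2 in cluster 11) and most LPS cells in cluster 11 (86 and 49 young, 239 and 70 old; 6, 10, 26 and 31 in cluster 9). If all their Sftpc came as free RNA from AE2-like cells of the same group, these sums would hold 6.43% of the AE2 level of each gene in young and 4.39% in old LPS libraries. The groups of a lane were pooled, so free RNA may also come from other groups. The values with free RNA taken off do not cover that. In the young 412 genes were higher and 257 lower, and in the old 446 and 275. Cholesterol synthesis genes rose at both ages: 12 of 19 in the young and 1 fell (13 and 1 adjusted over the list alone; median 1.08; camera adjusted p = 2.18e-08, and adjusted p = 0.0497 with an estimated correlation) and 11 of 19 in the old (15 and 0 adjusted over the list alone; median 1.12; adjusted p = 1.17e-12, and adjusted p = 0.0150 with an estimated correlation). They include Cyp51, a sterol demethylase (2.80 ± 0.42 log2, SE, in the young and 2.40 ± 0.43 in the old), and Idi1, of isoprenoid synthesis (1.56 ± 0.31 and 1.96 ± 0.32). In AE2-like cells that list did not pass after LPS at either age; the difference between the cell classes was not tested. Acute phase genes rose in 11 of 18 cases at each age (12 and 13 adjusted over the list alone, medians 2.76 and 3.23, camera adjusted p = 4.68e-14 and 5.54e-19, and adjusted p = 0.0324 and 0.0150 with an estimated correlation), such as ceruloplasmin, Cp, at 4.84 ± 0.19 and 3.90 ± 0.17, of which free RNA would be 0.824% and 0.609% after LPS. With free RNA taken off, the medians in the young and old are 1.81 and 3.16 for the acute phase list, 3.54 and 1.19 for interferon and 1.12 and 1.13 for cholesterol synthesis. Free RNA would be 86.3% and 50.8% of the Lcn2 after LPS. Interferon genes rose in 24 of 32 cases in the young (28 adjusted over the list alone, median 4.30, or 3.59 with 10 genes at the floor of 3 control UMIs, camera adjusted p = 2.60e-27, and adjusted p = 0.103 with an estimated correlation) and 15 of 32 in the old (17 and 1 lower adjusted over the list alone, median 1.35, camera adjusted p = 1.29e-14, and adjusted p = 0.196 with an estimated correlation), such as Irf7 at 5.44 ± 0.29 and 2.64 ± 0.23, and the cell cycle inhibitor Cdkn1c fell at -3.95 ± 0.42 and -3.76 ± 0.35.

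Between old and young ciliated-like cells, 20 genes were higher and 9 lower in controls and 21 higher and 66 lower after LPS. Lists lower in old controls were cholesterol synthesis (median -0.34, camera adjusted p = 0.00188), endoplasmic reticulum stress (-0.27, 0.00542) and ribosomal proteins (-0.13, 0.0242). With free AE2 RNA taken off, these medians in controls are -0.25, -0.21 and -0.02. Cholesterol synthesis was lower in the old after LPS too (-0.25, camera adjusted p = 0.00428). With an estimated correlation none of these passed (camera adjusted p = 0.235, 0.482, 0.681 and 0.204). Immediate-early and heat shock genes, which dissociation induces, were higher in old controls as a list (2 of 15 higher and 1 lower, 9 and 2 adjusted over the list alone, median 0.77, camera adjusted p = 4.94e-05, and adjusted p = 0.235 with an estimated correlation) and had a median interaction of -0.70 (camera adjusted p = 0.0121, and adjusted p = 0.320 with an estimated correlation). After LPS the old had less Gbp2 (-2.71 ± 0.20, adjusted p = 8.04e-11) and Igtp (-2.74 ± 0.23), and more of the chemokine Ccl20 (1.83 ± 0.26). The interaction passed in 7 genes higher and 10 lower, and the interferon list had a median interaction of -2.56 (6 of 32 lower, 20 adjusted over the list alone, a median of -2.43 with 10 genes at the floor, camera adjusted p = 5.13e-20, and adjusted p = 0.320 with an estimated correlation). MHC class I (-0.69, camera adjusted p = 3.77e-05), endoplasmic reticulum stress (0.64, 8.89e-05) and chemokines and cytokines (1.51, 0.0188) passed the interaction too. Each had adjusted p = 0.320 with an estimated correlation. Sftpc was 0.886% of the UMIs of ciliated-like cells in young controls and 0.303% after LPS, and 0.520% and 0.257% in the old. These fits were not repeated under the alternatives.

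Old control 2 held 321 alveolar macrophage-like cells among 1528, a share of 21.0%, against 0.417% to 3.65% in the other 7 libraries. A batch effect of the second lane would raise the share in its other libraries, where the highest was 2.82%, below the 3.65% of lane 1. Compared within groups, lane 2 was higher in young LPS (0.962% against 0.417%) and old LPS (2.61% against 0.748%). It was lower in young control (2.82% against 3.65%). A smaller effect of the lane therefore stays open. The filter on barcodes may have changed it, but with every deposited barcode the share was 17.1% there and at most 2.54% in the others. Age would raise the share in the other old control library too, where it was 2.92% (95% exact binomial interval 2.12% to 3.91%), against 2.82% and 3.65% in the young controls. Within lanes the share was higher in the old in 3 of 4 pairs. After LPS it was 0.748% in the old and 0.417% in the young in lane 1, and 2.61% and 0.962% in lane 2. A smaller difference with age therefore stays open. The sort for EpCAM should remove macrophages, so a difference in the sort between mice or days stays open and was not tested.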
